A study of Mus musculus with 22 samples.

How the data were processed

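The series holds 22 mouse libraries in 12 groups. Of these, 20 libraries in 10 groups were made with 3′READS, an assay that sequences the fragment next to the poly(A) tail and so gives the position of each RNA 3′ end and its number of reads. The other 2 are RNA-seq libraries of 3T3-L1 cells. Per the labels, 4sU libraries were made from RNA labelled for 1 h with 50 µM 4-thiouridine (4sU), a uridine analogue taken up into newly made RNA. Controls are labelled untreated, and no control siRNA is named. Groups came from the sample titles and labels, with 2 libraries in each 3′READS group and 1 in each RNA-seq group. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

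The deposited 3′READS files list a chromosome, a strand, a poly(A) site position and a read count, and the deposited RNA-seq files list a gene symbol and a read count. The authors left these counts unnormalized, as whole numbers whose totals differ between libraries. Cutadapt, Bowtie2 and STAR are named in the submitters' processing notes without versions or roles, and the genome build there is mm9. How sites were clustered and which annotation was used for RNA-seq are not given in the sources used here. The RNA-seq files list no gene below 5 counts, so an unlisted gene can have had a few reads and was entered as 0.

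The 3′READS files carry no gene names, and the gene table used here is for GRCm38.p6, another build than mm9. Coordinates were not converted, so poly(A) sites were given no gene name, gene size, intron or UTR. Tests of gene size in both assays and of gene lists for 3′READS, the class of intronic sites and the level of Pcf11 in those libraries were therefore not analysed here. In place of a gene stood a site group. Sites with at least 1 CPM (counts scaled to library size) in at least 2 libraries of a cell line were kept and chained on each strand over gaps of up to 5 kb. In place of intronic sites, the most 5′ used site of a group was set against its other used sites, where a used site held at least 5% of the group's reads. In place of 3′ UTR sites, the proximal and distal of the 2 most used sites were compared. In a site group with only 2 used sites both comparisons take the same reads, so their counts overlap and are not separate results. A site group can hold several genes or part of a gene, and the most 5′ site need not lie in an intron.

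Of the sites listed for C2C12, 39540 were kept in 18349 site groups, 8078 of them with 2 or more sites. For 4T1, 31049 sites were kept in 15744 site groups, and for NIH3T3, 30904 in 19059. The kept sites held at least 97.3% of each library's reads except in the 4T1 Pcf11-IPAKO libraries, where they held 93.7% and 93.0%.

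Counts were tested in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1), by quasi-likelihood F-tests after TMM scaling and filterByExpr with a minimum count of 10, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The 8 C2C12 siRNA libraries were fitted together, and the other cell lines and the differentiation series apart. Site use was tested with edgeR's diffSpliceDGE on the counts of sites within site groups. A standard error of a log2 fold change is its size divided by the square root of the F statistic. Other settings tried were DESeq2 1.42.0, library totals or DESeq2 size factors for scaling, no low-count filter, thinning of the 4T1 libraries, the replicate number as a block and each library left out in turn. Gaps of 2 and 10 kb, removal of mitochondrial sites and a block of 4sU with total RNA libraries of the same treatment and number were added after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The tests of levels and of site use, both stand-in comparisons and the remaining settings were fixed before the data were examined, for genes. The site group with its 5 kb gap and 1 CPM minimum, the mean distal use per library, the grouping of pairs by distance and the correlations of shifts were chosen afterwards.

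Replicate libraries differed by more than counting noise in every 3′READS group, with a chi-square per degree of freedom between 2.16 and 18.3. Each was counted as a sample, although such a spread can be technical and does not show that the libraries are independent. Where all libraries of a group were at 0, the fold is a lower bound against 3 counts over the group. Such floors, and all intervals of counts, cover counting error only, since reads amplified by PCR are not independent molecules. With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.333.

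The tests were tried on simulated counts with 200 changed site groups or pairs. Far more site groups passed in the data of C2C12 total RNA and differentiation. The adjusted p depends on the share changed, so recovery there can differ from that in the simulation. For C2C12 total RNA (11081 site groups), 54% of 2-fold and 90% of 4-fold changes in level were recovered. For NIH3T3 (13575 site groups) the shares were 8% and 60%, for 4T1 (10500 site groups) 8% and 74%, and for differentiation (11760 site groups) 68% and 92%. For pairs of sites, 4-fold changes were recovered at 32% in C2C12 total RNA (3106 pairs), 8% in NIH3T3 (3052 pairs), 8% in 4T1 (2741 pairs) and 42% in differentiation (3705 pairs). Every recovered change had the right direction. Unchanged site groups called for level numbered 5 in C2C12 total RNA, 3 in NIH3T3, 8 in 4T1 and 6 in differentiation. In 4T1 these 8 stood beside 4, 37 and 41 recovered changes of 2-fold, 4-fold and 8-fold. Unchanged pairs called numbered 1, 2, 0 and 2 in the same order of comparisons.

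For 3T3-L1, with 1 library per group, no test was made. The log2 ratio was taken of CPM after TMM scaling with 1 CPM added to each side, among 11253 genes with at least 10 counts over both libraries. Its 95% interval comes from the exact binomial interval of the raw counts. The median of each fixed gene list was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Of 11355 symbols, 11123 matched the gene table and 222 its synonyms. Counts of histone and ribosomal protein genes are uncertain, as reads of near-identical copies can be split between them. For the same reason, and because no strand rule is stated, overlapping and antisense genes cannot be told apart.

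Named items followed a rule fixed beforehand. In 3T3-L1 these are Pcf11, the 6 highest and 6 lowest ratios among genes with at least 100 counts, and up to 4 members of a list by size of ratio. Symbols of Gm with a number, ending in Rik, or starting with LOC, Mir or Snor were not named. For 3′READS the rule asked for the largest changes in level with a mean of at least 5 CPM and no overlap between groups, and the largest changes in percent use with at least 100 reads. As positions without gene names they were held to at most 2 per direction. Correlations across site groups or pairs are descriptions with intervals from leaving out each chromosome in turn, since site groups are not independent replicates. Of these, 18 were computed, and those for the 2 most used sites were computed again after the median shift of each of 20 equal bins of distance was taken off in each comparison, a step tried first on simulated shifts. Site groups of different cell lines were matched where their spans overlapped within 24 nt, and pairs where both positions were identical.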

Results

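Poly(A) site use and RNA levels were measured in mouse cell lines, in libraries labelled for Pcf11 and in controls. PCF11 is a protein of the cleavage and polyadenylation machinery that also acts in transcription termination. C2C12 (myoblasts), NIH3T3 (embryonic fibroblasts) and 3T3-L1 (preadipocytes) libraries labelled siPcf11 were set against controls, and 4T1 mammary carcinoma cells labelled Pcf11-IPAKO against 4T1 controls. As controls are labelled untreated and no control siRNA is named, an effect of siRNA transfection itself cannot be told apart from one of Pcf11 in any siPcf11 comparison. C2C12 cells were also compared before and after differentiation. The 3′READS libraries held 1887532 to 4432717 reads. The RNA-seq libraries held 8573956 reads (control) and 6992460 reads (labelled siPcf11). Positions are in mm9 as listed in the deposited tables, which pair no gene name with a poly(A) site, so the target gene could be checked only in 3T3-L1.

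In C2C12 total RNA, the libraries labelled siPcf11 used distal poly(A) sites more. The distal of the 2 most used sites took 54.99% ± 0.295 of the reads of a pair on average under siPcf11 and 50.0% ± 0.178 in controls (SD, n = 2, 3106 pairs). Both siPcf11 libraries lay above both controls, which gives the smallest exact permutation p possible, 0.333. Among the pairs, 331 moved to the distal and 97 to the proximal site (edgeR, Benjamini-Hochberg adjusted p under 0.05). The median change in distal use was 1.36 percentage points for sites under 200 nt apart and 10.2 percentage points for sites at least 2000 nt apart. Use moved away from the most 5′ site in 300 site groups and toward it in 74 of 3012. These counts overlap with those of pairs, as site groups with only 2 used sites enter both with the same reads. At chromosome 10, plus strand, distal use of the sites at 52156572 and 52159987 was 89.9% ± 6.98 under siPcf11 and 19.2% ± 11.4 in controls (n = 2, adjusted p = 0.000275). At chromosome 2, minus strand, distal use of the sites at 104269935 and 104266638 was 32.6% ± 2.20 under siPcf11 and 91.1% ± 0.227 in controls (n = 2, adjusted p = 2.84e-05). Of 7651 sites tested singly, 1226 changed in use, in 892 of 3168 site groups. With gaps of up to 2 kb, which leave fewer sites per group, 244 pairs and 205 most 5′ sites passed, and without siPcf11 replicate 2 these counts were 283 and 230.

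Levels changed at 5735 of 11081 site groups in C2C12 total RNA, 2688 higher and 3047 lower under siPcf11. Of these, 1132 were at least 2-fold higher and 1973 at least 2-fold lower. With library totals as the only scaling, 1989 were higher and 3675 lower, while without siPcf11 replicate 1 more were higher (2802 against 2437 lower), as without siPcf11 replicate 2 (2625 against 2304). The site group at 3232930 to 3237733 on chromosome 10, plus strand, had 71 reads under siPcf11 and 1 in controls. Scaled to library size, the ratio was 87.3 (counting interval 15.2 to 3495, edgeR adjusted p = 7.38e-16). The site at 94506310 on chromosome 11, minus strand, had no read under siPcf11 and 52 in controls, and was at least 14.1-fold lower (adjusted p = 1.35e-10). Reads on the plus strand of the mitochondrial genome were at 37819 ± 8071 CPM under siPcf11 and 25771 ± 1694 CPM in controls (n = 2, log2 fold change 0.55, SE 0.10, edgeR adjusted p = 1.11e-07). This SE comes from the fit of all 8 C2C12 siRNA libraries, not from the spread of these groups alone. Without TMM scaling the groups lay close together. Both mitochondrial strands held 3.668% and 4.772% of reads under siPcf11 and 3.179% and 3.605% in controls. On the minus strand the log2 fold change was 0.21 (edgeR adjusted p = 0.0581).

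In 4sU RNA, which the series design ties to the stability of isoforms, the distal site took 54.5% ± 0.0491 under siPcf11 and 50.7% ± 0.222 in controls (SD, n = 2, 3073 pairs; exact permutation p = 0.333, the smallest possible). Here 260 pairs moved to the distal and 89 to the proximal site, and use moved away from the most 5′ site in 214 site groups and toward it in 67 of 3012. Of 7703 sites tested singly, 1058 changed in use. At chromosome 19, plus strand, distal use of the sites at 4002102 and 4007005 was 82.5% ± 13.0 under siPcf11 and 15.0% ± 0.480 in controls (n = 2, adjusted p = 0.000271). At chromosome 11, minus strand, distal use of the sites at 100957839 and 100953513 was 1.32% ± 1.86 under siPcf11 and 55.5% ± 1.13 in controls (n = 2, adjusted p = 1.23e-07). Levels changed at 5939 of 11081 site groups, 3158 higher and 2781 lower, or 1916 higher and 4001 lower with library totals. More were lower also without siPcf11 replicate 1 (2264 higher, 2496 lower) or 2 (2433 higher, 2455 lower) and with only the 4 compared libraries (2909 higher, 3060 lower). The site at 10055501 on chromosome 10, minus strand, had 38 reads under siPcf11 and none in controls and was at least 19.1-fold higher (adjusted p = 3.41e-10). The site group at 53518501 to 53519581 on chromosome 19, minus strand, had no read under siPcf11 and 126 in controls and was at least 27.8-fold lower (adjusted p = 1.38e-19). With any of the 4 libraries left out, 564 to 671 single sites and 147 to 183 most 5′ sites passed. Left-out libraries lowered the counts of pairs to 181 (siPcf11 replicate 1), 211 (siPcf11 replicate 2) and 232 (control replicate 2), and with gaps of up to 2 kb 212 passed.

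The responses in 4sU and total RNA were alike in direction. Across 11081 site groups the log2 changes had a Pearson's r of 0.833 (Spearman's rho 0.841), and of 4508 site groups called in both, 2189 were higher and 2305 lower in both. A test of the difference between the responses called 95 site groups, 77 with a higher and 18 with a lower change in 4sU RNA. Left-out libraries lowered the count to 24 (siPcf11 4sU replicate 1), 40 (siPcf11 4sU replicate 2), 25 (control 4sU replicate 2), 48 (siPcf11 total replicate 1), 33 (control total replicate 1) and 62 (control total replicate 2). Without siPcf11 4sU replicate 1, 7 had the higher and 17 the lower change, without siPcf11 4sU replicate 2, 17 and 23, without siPcf11 total replicate 1, 9 and 39, and without siPcf11 total replicate 2, 44 and 42. DESeq2 called 32, and with DESeq2 size factors in edgeR 46 had a higher and 23 a lower change. For use of the most 5′ site, 0 of 3005 site groups differed between the responses in edgeR's test, with 84 at an unadjusted p under 0.05. Between 4sU and total RNA of control cells, levels differed at 3087 site groups, 1241 higher and 1846 lower in 4sU RNA (1573 without control 4sU replicate 2 and 1831 without control total replicate 1). Reads on the minus strand of the mitochondrial genome were higher in 4sU RNA, with 31137 ± 2853 CPM in 4sU RNA and 7098 ± 1065 CPM in total RNA (n = 2, log2 fold change 2.13, SE 0.10, adjusted p = 8.93e-70).

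In NIH3T3 the mean distal use was 54.9% ± 0.699 under siPcf11 and 49.8% ± 0.131 in controls (SD, n = 2, 3052 pairs; exact permutation p = 0.333, the smallest possible). Individual pairs rarely passed the test, with 3 moved to the distal and 0 to the proximal site in edgeR and 185 pairs at an unadjusted p under 0.05. At chromosome 15, minus strand, distal use of the sites at 96827199 and 96825253 was 35.1% ± 4.24 under siPcf11 and 7.67% ± 0.169 in controls (n = 2, adjusted p = 0.0329). At chromosome 7, minus strand, distal use of the sites at 129132279 and 129130236 was 24.7% ± 18.7 and 0.941% ± 0.520 (n = 2, adjusted p = 0.0333). For levels, edgeR called 0 of 13575 site groups, with 2268 at an unadjusted p under 0.05, while DESeq2 called 332. Use moved away from the most 5′ site in 3 site groups of 2955 and toward it in 0. For single sites edgeR called 0 of 7293, with 523 at an unadjusted p under 0.05. Without siPcf11 replicate 1 edgeR called 5000 levels, 1436 single sites, 300 most 5′ sites and 420 pairs. Without siPcf11 replicate 2 it called 1780, 200, 58 and 71, and without either control 0 of each. With a siPcf11 library left out, the fit takes the spread from the controls alone. Across 1189 pairs at identical positions, the log2 shift had an r of 0.503 with that in C2C12 total RNA (rho 0.442). A test of the difference in level response between the 2 cell lines called 528 of 14494 site groups, but 0 when any C2C12 library was left out, 20 without either NIH3T3 control, 3646 without NIH3T3 siPcf11 replicate 1 and 2223 without replicate 2.

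In 4T1 cells the Pcf11-IPAKO libraries used distal sites less. Mean distal use was 49.9% ± 0.776 in Pcf11-IPAKO and 53.3% ± 0.480 in controls (SD, n = 2, 2741 pairs; exact permutation p = 0.333, the smallest possible), and 33.6% of pairs had a log2 shift to the distal site. Single pairs again rarely passed, with 3 moved to the distal and 2 to the proximal site. Use moved toward the most 5′ site in 1 site group of 2652 and away from it in 0 (edgeR, 59 at an unadjusted p under 0.05), and 7 were called without Pcf11-IPAKO replicate 2 and 0 without any other library. In that site group, on chromosome 8, plus strand, the sites beyond the most 5′ one at 13877797 took 10.3% ± 5.43 of reads in Pcf11-IPAKO and 57.1% ± 1.63 in controls (n = 2, adjusted p = 0.0398). Of 6667 sites tested singly, 26 changed in use, and 7 to 15 with any library left out. At chromosome 11, minus strand, distal use of the sites at 69486617 and 69482748 was 58.8% ± 6.53 in Pcf11-IPAKO and 12.2% ± 6.59 in controls (n = 2, adjusted p = 0.0465). At chromosome 4, plus strand, distal use of the sites at 122971814 and 122976171 was 3.65% ± 2.10 and 51.1% ± 6.54 (n = 2, adjusted p = 0.0199). With libraries left out in turn the number of pairs was 1 (Pcf11-IPAKO replicate 1), 8 (Pcf11-IPAKO replicate 2), 0 (control replicate 1) and 3 (control replicate 2), and without Pcf11-IPAKO replicate 2 they were 2 distal and 6 proximal. Levels changed at 437 of 10500 site groups, 385 higher and 52 lower, all with a fitted change of at least 2-fold. The split was 287 and 45 without Pcf11-IPAKO replicate 1, 308 and 119 without Pcf11-IPAKO replicate 2, 439 and 121 without control replicate 1, and 363 and 81 without control replicate 2. With no library left out and the replicate number as a block it was 984 and 606, though no label gives same-numbered libraries a shared origin. The site group at 18762793 to 18763369 on chromosome 10, minus strand, had 66 reads in Pcf11-IPAKO and none in controls and was at least 23.2-fold higher (edgeR adjusted p = 0.00529). The site at 15846074 on chromosome 4, minus strand, had 1 read in Pcf11-IPAKO and 151 in controls. Scaled to library size, controls had 143 times as many (counting interval 25.3 to 5682, edgeR adjusted p = 0.00186). The Pcf11-IPAKO libraries also held a larger share of reads at sparsely read positions, 6.66% ± 0.538 against 2.35% ± 0.449 (n = 2).

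**Figure D1:**
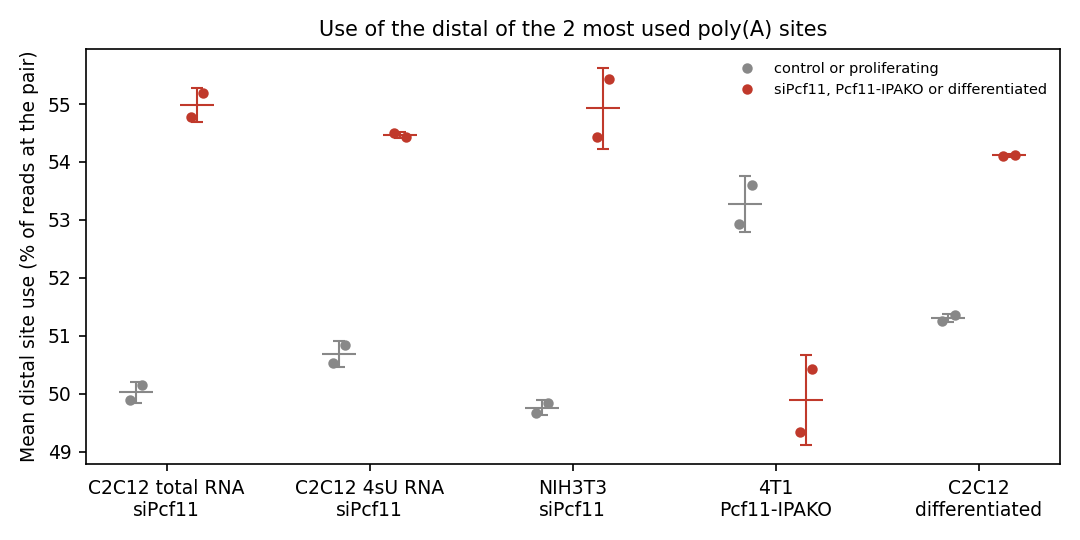
Mean use of the distal of the 2 most used poly(A) sites, in percent of the reads of a pair, for each library (points) with the group mean (horizontal line) and SD (bars, n = 2); the vertical axis does not start at 0. The siPcf11 and differentiated libraries lie above their controls or proliferating cells and the Pcf11-IPAKO libraries below, with means of 54.99% against 50.0% in C2C12 total RNA and 49.9% against 53.3% in 4T1.

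Differentiation of C2C12 cells was accompanied by higher use of distal sites, 54.1% ± 0.0213 in differentiated and 51.3% ± 0.0660 in proliferating cells (SD, n = 2, 3705 pairs; exact permutation p = 0.333, the smallest possible). Here 180 pairs moved to the distal and 98 to the proximal site, and use moved away from the most 5′ site in 125 site groups and toward it in 71 of 3573. Of 9177 sites tested singly, 780 changed in use. At chromosome X, plus strand, distal use of the sites at 98643930 and 98648880 was 81.5% ± 1.29 in differentiated and 0.396% ± 0.231 in proliferating cells (n = 2, adjusted p = 1.07e-31). At chromosome 9, minus strand, distal use of the sites at 66875781 and 66870397 was 28.5% ± 3.14 and 98.4% ± 0.342 (n = 2, adjusted p = 1.77e-20). Levels changed at 7344 of 11760 site groups, 3841 higher and 3503 lower in differentiated cells, or 3333 higher and 4169 lower with library totals, so which direction holds more rests on the scaling. The site group at 136188944 to 136189127 on chromosome 1, plus strand, had 9853 reads in differentiated and none in proliferating cells and was at least 3185-fold higher (adjusted p = 3.88e-49). The site at 172215482 on the same chromosome and strand had no read in differentiated and 99 in proliferating cells and was at least 34.0-fold lower (adjusted p = 2.61e-14). Without differentiated replicate 1 or 2, 401 and 408 single sites and 99 and 97 most 5′ sites passed. Left-out libraries lowered the count of pairs to 141 (differentiated replicate 1), 127 (differentiated replicate 2) and 185 (proliferating replicate 1), and with gaps of up to 2 kb 136 passed.

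The siPcf11 response in C2C12 total RNA and the differentiation change share no library. Across 10395 site groups their log2 changes had an r of 0.238 (interval 0.216 to 0.260, rho 0.223). Of 3667 site groups called in both, 986 were higher and 1383 lower in both, 662 were higher under siPcf11 and lower in differentiation, and 636 the reverse (Fisher's exact test, two-sided p = 1.33e-66). Independent lists would give 723 higher and 972 lower in both, 826 higher under siPcf11 and lower in differentiation, and 851 the reverse. Fisher's test compares directions among the site groups called in both, not the size of the overlap. Site groups are not independent replicates, so this p only describes how far the directions agreed.

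**Figure D2:**
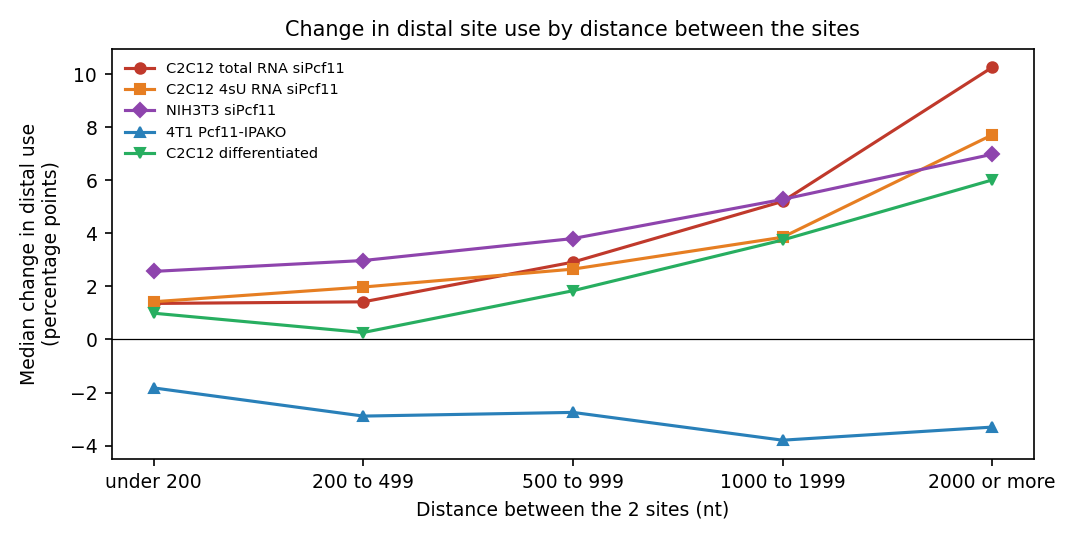
Median change in distal use, in percentage points, of pairs of sites grouped by the distance between the sites in nt, for the 5 comparisons (lines join the medians; no error is drawn). Under siPcf11 in C2C12 total RNA the median rises from 1.36 for sites under 200 nt apart to 10.2 at 2000 nt or more, and in 4T1 Pcf11-IPAKO it lies between -1.82 and -3.79.

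In 3T3-L1 cells, Pcf11 was not lower in the library labelled siPcf11. It had 939 counts in the control and 840 in the library labelled siPcf11, 112% of the control after scaling (log2 ratio 0.16, counting interval 0.03 to 0.30). The target gene thus goes against the label, and every direction below is that of the library labelled siPcf11. The difference between these libraries has no replicate check, and the intervals compare libraries, not conditions. Among 9143 genes with at least 100 counts, 5 were at least 2-fold higher and 20 at least 2-fold lower. Among the symbols kept for naming, the highest log2 ratios were those of Asic1, an acid-sensing ion channel (1.36), Selp, P-selectin (1.21), and Tmcc3 (1.201). Next came Vwf, von Willebrand factor (1.14), Creld1 (1.04) and Aoc2 (0.98). The lowest among these symbols were those of Spata24 (-1.46), Pgghg (-1.34), Eva1b (-1.25), Txlng (-1.22), Dpt, the matrix protein dermatopontin (-1.19), and U2af1l4 (-1.17).

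Interferon response genes stood apart in the library labelled siPcf11. Whether transfection alone would raise them cannot be told, as the control is labelled untreated. Of 19 counted members, 18 had a log2 ratio above 0 and 9 were at least 1.5-fold higher, with a median of 0.42 at percentile 100 of matched random lists. The transcription factor subunit Irf9 had a log2 ratio of 0.77 (interval 0.49 to 1.12), Oasl2 of 0.76, the ubiquitin-like Isg15 of 0.72 and Ifit3 of 0.60. Extracellular matrix and adhesion genes had a median of 0.13 (percentile 99.5, 23 of 32 above 0), with Thbs1 at 0.41 and Cdh2 at 0.39. Respiratory chain genes had a median of 0.10 (percentile 99.9, 46 of 69 above 0), although the members with the largest ratios, Ndufa3 (-0.73) and Ndufa11 (-0.57), were lower. Cytosolic ribosomal protein genes had a median of 0.10 (percentile 99.5, 31 of 49 above 0). Histone genes had a median of -0.21 (percentile 7.37), with 4 of 15 above 0.

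The other lists with a percentile lay between percentile 14.4 and 84.4 of random lists. Cleavage and polyadenylation factors had a median of 0.05 (percentile 78.3), with Cpsf4 at -0.44 and Cpsf1 at -0.36. Transcription elongation and termination genes had a median of -0.02 (percentile 23.7), and splicing factors of -0.02 (percentile 14.4). Cell cycle genes had a median of 0.01 (percentile 46.7), with Tyms at -0.51 and Ccnd1 at 0.37. The p53 targets had a median of 0.03 (percentile 63.7), stress and unfolded protein response genes of -0.01 (percentile 32.5), and immediate early genes of 0.03 (percentile 64.5). Among cell type markers, the median was 0.02 for adipocyte genes (percentile 54.7), although the lipid droplet gene Plin4 had a log2 ratio of -0.92 (interval -1.08 to -0.77). It was 0.02 for fibroblast (percentile 50.2), 0.12 for myoblast identity (percentile 84.4) and 0.06 for muscle differentiation genes (percentile 68.5). Too few markers were counted for a percentile in epithelial (4 genes, median -0.38), immune (4 genes, 0.44) and endothelial cells (2 genes, 0.39).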

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

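In this part, the tests on whole chromosomes, on scaling in 4T1 and on a weaker knockdown and another source in NIH3T3 were chosen after the result was seen, as was the comparison with the opposite strand in 4T1.

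The 4T1 Pcf11-IPAKO libraries held 6.66% of their reads at sparsely read positions, outside the sites that were tested, against 2.35% in controls. Sequencing depth is argued against, since after thinning to the smallest library the ratio of the shares was 3.01. Priming on genomic DNA would put reads on both strands alike. It cannot be told apart from other sources, because 59.5% and 60.4% of these reads upstream of a strong site lay on its strand. That is more than even strands would give and less than the share set beforehand to exclude it. Controls had higher shares, 68.4% and 68.9%, and of the excess over controls upstream, 55.9% lay on the strand of the site. Downstream the shares on that strand were 52.3% and 53.4% in Pcf11-IPAKO and 57.0% and 56.6% in controls. Early RNA ends or priming on unspliced RNA, which need reads on the strand of the gene, met the bound set beforehand with shares at least 2.30 times those of controls, which is consistent with them but does not set them apart from genomic DNA, as reads on the opposite strand rose too and were not placed in transcription units of their own: 1 to 20 kb upstream the share of all reads grew by 0.744 percentage points on the strand of the site (2.75-fold) and by 0.587 on the opposite strand (4.02-fold), and 1 to 20 kb downstream it was 0.810% against 0.359% in controls on the strand of the site and 0.721% against 0.273% on the opposite strand. An effect of the Pcf11-IPAKO edit stays open and was not tested apart from these.

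In NIH3T3, 0 site groups were called although leaving out either siPcf11 library gave 1780 or more. Depth is argued against, since after thinning the SD between the siPcf11 libraries was 2.08 times that between controls. A weaker knockdown in replicate 1 cannot be told apart from other sources, because the level of Pcf11 was not analysed in these libraries. Replicate 1 had the smaller spread of level changes. It also had the smaller gain in mean distal use over pairs, with a ratio of gains of 1.21 (interval 1.03 to 1.39). That interval comes from leaving out chromosomes and does not cover the spread between libraries. With the reads of all pairs pooled the order turned, at 54.8% distal in replicate 1 and 53.9% in replicate 2 (controls 49.2% and 49.7%). RNA from another source stays open too: 0 of 3190 listed sites at 50 CPM or more were 8-fold higher in a siPcf11 library than in every other, and reads of 4T1 or differentiated C2C12 cells mixed into a control gave 23 and 32 such sites at 20% but 1 and 4 at 5%, so a small share or a source close to NIH3T3 would not show. What makes these libraries differ stays open.

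In 4T1, 385 site groups were higher and 52 lower in Pcf11-IPAKO, and these counts were 287 and 45 without Pcf11-IPAKO replicate 1, 308 and 119 without Pcf11-IPAKO replicate 2, 439 and 121 without control replicate 1, and 363 and 81 without control replicate 2. For gains or losses of whole chromosomes, the median change of each chromosome was taken off, and 100% of the called site groups still differed at least 2-fold. That share decides nothing, as all 437 were at least 2-fold changed before, with a median absolute log2 change of 3.25. Chromosome medians departed from that of all site groups by -0.26 on chromosome 8, -0.25 on chromosome 17, 0.22 on chromosome 16 and less on the other nuclear chromosomes. Shifts of that size are far smaller than the called changes. Changes of chromosome segments were not tested. Sparse reads cannot be told apart from other sources. The share of higher groups that were lone sites under 1 CPM in both controls was 8.57%. It could not have reached the bound set, with 86 lone sites among the 385. With any number of sites, 121 of the 385 (31.4%) were under 1 CPM in both controls. The higher groups had a median of 3 sites (2 among those tested) and 1.97 CPM in controls. At 7 or more sites, 70 were higher and 2 lower. The choice of scaling as the whole cause is argued against, since at least 88.1% of calls were higher with library totals or DESeq2 size factors. With the replicate number as a block, 984 were higher and 606 lower, so 61.9% were higher. Same-numbered libraries deviated together, with a correlation of 0.384, but no label gives them a shared origin, so whether the block applies cannot be told. Differences between edited and control cells, through the edit or through how the cells were derived, may remain and were not tested.

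A test of the difference between the siPcf11 responses of 4sU and total RNA in C2C12 called 95 site groups, and 24, 40, 25, 48, 33 and 62 without siPcf11 4sU replicate 1, siPcf11 4sU replicate 2, control 4sU replicate 2, siPcf11 total replicate 1, control total replicate 1 and control total replicate 2, with the directions turned without the first, the second or the fourth of these and nearly even (44 higher, 42 lower) without siPcf11 total replicate 2. A test of the difference between the siPcf11 responses of NIH3T3 and C2C12 total RNA called 528 site groups, 0 without any C2C12 library, 20 without either NIH3T3 control, and 3646 and 2223 without NIH3T3 siPcf11 replicate 1 and 2.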

How the results depend on the processing

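Gaps of 2 and 10 kb, removal of mitochondrial sites, the block for the correlation and the block of 4sU with total RNA were chosen after the data were seen; the other alternatives were planned. Of 296 alternative values, 201 stayed within the limits set (1.5 times for a count) and 95 did not, and the cause was not tested except where the construction gives it. Counts of changed levels in C2C12 total RNA, C2C12 4sU RNA and differentiation stayed within 1.5 times under every alternative run, with DESeq2 calling 4428, 4480 and 5662. The r between siPcf11 and differentiation lay between 0.206 and 0.245 with libraries left out and was 0.360 for site groups called in both.

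With gaps of up to 2 kb, which leave fewer sites per group, counts of changed single sites, most 5′ sites and pairs were 713, 205 and 244 in C2C12 total RNA, 649, 162 and 212 in 4sU RNA, 435, 98 and 136 in differentiation, and 12, 2 and 2 in 4T1. With gaps of up to 10 kb they were 8, 7 and 8 in NIH3T3, and in 4T1 0 most 5′ sites and 2 pairs passed. In NIH3T3, DESeq2 called 332 levels, and 9 single sites passed with a minimum use of 1% and 1 with 10%. In 4T1, 8 single sites passed with a minimum use of 10%, 17 with at least 20 counts and 17 after thinning, and with at least 20 counts 0 most 5′ sites and 2 pairs passed. The difference between 4sU and total responses was called at 32 site groups by DESeq2, and that between NIH3T3 and C2C12 at 280 without a low-count filter. In 3T3-L1 the log2 ratio of Pcf11 was 0.13 with library totals and 0.16 with a prior of 5 CPM, and with at least 100 counts the list medians were -0.32 for histone and 0.13 for adipocyte genes.

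With each library left out in turn, where the lone library is taken to vary like the other groups, the ranges for levels, single sites, most 5′ sites and pairs were as follows. In C2C12 total RNA they were 4872 to 5239, 824 to 892, 230 to 266 and 283 to 327. In 4sU RNA they were 4760 to 5001, 564 to 671, 147 to 183 and 181 to 238. In NIH3T3 they were 0 to 5000, 0 to 1436, 0 to 300 and 0 to 420. In 4T1 they were 332 to 560, 7 to 15, 0 to 7 and 0 to 8. In differentiation they were 6243 to 7123, 401 to 586, 97 to 171 and 127 to 215. The difference between 4sU and total responses ranged from 24 to 92, 4sU against total RNA in controls from 1573 to 2608, and NIH3T3 against C2C12 from 0 to 3646.

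Same-numbered 4T1 libraries deviated together, with a correlation of 0.384, but 2 pairs whose labels give no shared origin are too few to show pairing. Between treated and control groups elsewhere the correlation was 0.0520 to 0.0814, and between 4sU and total RNA it was 0.0593 in C2C12 controls and -0.0102 under siPcf11. With the replicate number as a block, 4T1 gave 1590 levels (984 higher and 606 lower, so 61.9% higher against 88.1% without the block), 66 single sites, 23 most 5′ sites and 18 pairs, the difference between 4sU and total responses 216 (180 higher and 36 lower), and NIH3T3 against C2C12 263. Titles call the total RNA libraries of C2C12 input, and with 4sU and total RNA of the same treatment and number as a block, the difference between responses was 140 (115 higher and 25 lower) and controls gave 3192. The block left the other counts within 1.5 times: C2C12 total RNA 5880, 1284, 398 and 462, 4sU RNA 6069, 1127, 300 and 378, NIH3T3 0, 0, 3 and 2, differentiation 7445, 857, 221 and 315, and controls 3342, with the correlation at 0.238. No paired analysis was possible for 3T3-L1 because each group has 1 library. Alternatives of the gene size tests, and of the gene list tests for 3′READS, were not run, as those tests were not analysed here. Simulated 2-fold changes in level were recovered at 8% in NIH3T3 and 4T1, where the common coefficient of variation between replicates was 0.256 and 0.267, and at 54% in C2C12 total RNA, where it was 0.0858. Depth limits values of site groups with few reads, such as folds against 0 reads, which are lower bounds.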

Other observations

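In this part, the tests of reads around strong sites under siPcf11, the split by number of sites, the correlations after removal of distance and the mitochondrial values were chosen after the results were seen.

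Reads at sparsely read positions 1 to 20 kb from strong sites (at least 10 CPM) moved with siPcf11. Upstream on the strand of the site, their share of all reads was 0.284% ± 0.00558 under siPcf11 and 0.389% ± 0.00975 in controls in C2C12 total RNA (SD, n = 2), 0.312% and 0.413% in 4sU RNA, and 0.240% and 0.399% in NIH3T3. In differentiation it was 0.294% in differentiated and 0.346% in proliferating cells. In each of these comparisons the libraries of the groups did not overlap. The opposite strand upstream was lower too, at 0.0923% under siPcf11 and 0.0951% in controls in total RNA, 0.124% and 0.140% in 4sU RNA, and 0.119% and 0.151% in NIH3T3. There too the libraries did not overlap, while in differentiation they did (0.0915% and 0.0921%). Downstream on the strand of the site the share in C2C12 total RNA was 0.331% ± 0.00623 under siPcf11 and 0.243% ± 0.00652 in controls (n = 2). Downstream on the opposite strand it was 0.171% and 0.190%.

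The plus strand of the mitochondrial genome was higher in differentiated than in proliferating C2C12 cells, 42606 ± 1777 against 28051 ± 769 CPM (n = 2, log2 fold change 0.60, SE 0.09, edgeR adjusted p = 4.54e-08), and in 4sU RNA under siPcf11 the log2 fold change was 0.60 (SE 0.10, adjusted p = 9.61e-09). In NIH3T3 it was 0.04 (SE 0.25, adjusted p = 0.957) and in 4T1 Pcf11-IPAKO 0.35 (SE 0.40, adjusted p = 0.764). On the minus strand it was -0.03 in differentiation (edgeR adjusted p = 0.825) and 0.38 in 4sU RNA under siPcf11 (adjusted p = 0.00044). It was -0.28 there in NIH3T3 (adjusted p = 0.543) and 1.52 in 4T1 Pcf11-IPAKO (adjusted p = 0.209). Under siPcf11 in C2C12 total RNA, the median log2 change in level was 0.08 for 3862 site groups of 1 site and -0.15 for 678 site groups of 7 or more sites. This fall was not particular to siPcf11, as the medians were 0.098 and -0.095 in differentiation. They were 0.16 and -0.05 in 4sU RNA, 0.06 and -0.02 in NIH3T3, and the other way, -0.04 and 0.16, in 4T1 Pcf11-IPAKO.

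A hypothesis is that siPcf11 leaves more RNA ends downstream of strong sites. The lowest ratio of siPcf11 to control shares downstream was 1.197 over total and 4sU RNA in C2C12. Every siPcf11 library lay above every control of the same RNA, as the hypothesis asks. In NIH3T3 the ratio was 1.01, short of the bound set, which goes against a higher share there. Of the downstream reads at such positions in NIH3T3, 60.8% and 62.5% lay on the strand of the site under siPcf11 and 54.8% and 54.9% in controls, as the share on the opposite strand was lower (0.190% against 0.249% of all reads).

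A second hypothesis is that the pairs of sites that moved to the distal site under siPcf11 moved to the proximal site in 4T1 Pcf11-IPAKO. Across 1238 pairs at identical positions in C2C12 total RNA and 4T1 the log2 shifts had an r of -0.196 (interval -0.270 to -0.121, rho -0.201), which is consistent with it but weak. Across 1122 pairs in NIH3T3 and 4T1 r was -0.193 (rho -0.196). A general shift in opposite directions that changes with the distance between sites could give this sign. It is argued against as the whole cause, since r was -0.190 (interval -0.262 to -0.119) after the median shift of pairs at a like distance was taken off in each comparison. Other properties that pairs share, such as their use in controls, were not tested.

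Log2 shifts of pairs under siPcf11 in C2C12 total RNA had an r of 0.503 with those in NIH3T3 (interval 0.450 to 0.556, rho 0.442, 1189 pairs) and of 0.234 with those in differentiation (interval 0.158 to 0.310, rho 0.168, 2579 pairs). With the median shift at a like distance taken off, r was 0.482 (interval 0.426 to 0.537) and 0.208 (interval 0.131 to 0.286), so distance alone is argued against, while other shared properties of pairs were not tested. Of 84 pairs called both under siPcf11 and in differentiation, 56 moved to the distal and 13 to the proximal site in both. The shift to the distal site had little relation to level in C2C12 total RNA, with an r of 0.0796 (interval 0.0257 to 0.134, rho 0.0492, 3106 site groups), an interval that excludes 0.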
